A study of Homo sapiens with 2 samples.

How the data were processed

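RNA of 2 cultures of NUGC4 cells, a human gastric cancer cell line, was measured on expression arrays. One culture received a control siRNA and the other an siRNA against ANO5 (anoctamin 5), each at 20 nmol/l and transfected 24 h after seeding, per the labels' protocols. Total RNA was extracted with a column kit and labelled with biotin, per the labels' protocols. The 2 groups thus hold 1 array each, and the number of arrays limits the precision: no spread between replicates, standard error or p-value can be had, and none is given.

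The deposited table holds 1 value per array for each of 17345 transcript clusters, the probe groups by which the array reads a gene. The values have 2 decimals and run from 2.13 to 18.15. They were read as log2 signal as the authors deposited them, because of this range. The submitters' processing notes name Agilent Feature Extraction 12.0.3.1, whereas the cluster identifiers have the form of another maker's arrays. The summary of probes, the background correction, the normalization, the genome build and any log base are not given in the sources used here. On the deposited log2 scale the arrays had medians of 7.69 (control) and 7.68 (ANO5 siRNA), and their 75th percentiles over the named genes differed by 0.02. No column of values was left unused. No detection call was used, so that a fold against a value near background cannot be told from a lower bound.

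Gene names came from the platform's annotation table. Of the clusters, 14544 had 1 gene symbol, 0 had several and 2801 had none there. All 14544 matched a current human gene record by Entrez identifier, and 0 symbols changed by this match. The build of the array's clusters is not given in the sources used here, so no coordinates are reported. For the 16 genes with more than 1 cluster, the cluster with the highest mean of both arrays was used. This gave 14526 genes. Genes whose mean over both arrays lay at or above the 33rd percentile (6.05 on the log2 scale) formed the measured range of 9735 genes.

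The choices in this paragraph were made before the data were examined. Values were to be used as deposited unless the arrays' 75th percentiles differed by over 0.1 on the log2 scale, which they did not. All differences are the ANO5 siRNA array minus the control siRNA array. Genes were counted as higher or lower by a fixed rule of size, 2-fold (log2 difference of 1) for all measured genes and 1.5-fold for members of gene lists. For each of 32 gene lists the median difference of the measured members was set among the medians of 10000 random lists of the same size, matched on mean level in 20 bins. A list was said to stand apart where its percentile lay under 2.5 or over 97.5. By chance 1.6 of 32 lists would. Percentiles describe these 2 arrays and are not p-values, and random lists do not carry the co-regulation that members of a pathway share. The lists covered the cell cycle, stress responses, metabolism, cell identity, signalling, the anoctamins and other chloride channels, the RNA interference machinery, housekeeping genes and markers of other cell types.

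Named genes followed a rule fixed at the same time. It took every anoctamin in the table, the 12 measured genes with the largest positive and the 12 with the largest negative difference, and from each list up to 2 members each way (4 for cell cycle lists). It also took a fixed set of cell cycle and housekeeping genes. From the 2 sets of 12 it left out 107 measured genes with symbols of non-coding or uncharacterised loci, and would have left out genes whose clusters disagreed in direction, of which there were 0. One gene of the fixed set and the results of 1 of the gene lists are not reported here.

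The list percentiles were tested on simulated data with the 9735 measured genes' levels and spread and lists of 25 genes. Without a planted shift 3.5% of 200 lists stood apart. With planted log2 shifts of 0.3, 0.5 and 1, 42.5%, 81% and 100% did, all in the planted direction. The simulated differences were independent normal draws, without co-regulation of members or the larger tails of the real differences. These rates therefore do not carry over to lists of co-regulated genes or to smaller lists. Alternatives were 4 other scalings of the arrays, the median over a gene's clusters, no filter and a filter at the 50th percentile, thresholds of 1.5-fold and 3-fold, a pseudocount, the list mean, unmatched random lists and lists without shared members. Loess fits used a span of 0.4. Python 3.11.15, numpy 2.4.6 and pandas 2.3.3 were used.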

Results

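Gene expression was compared between NUGC4 gastric cancer cells given an siRNA against ANO5 and NUGC4 cells given a control siRNA, with 1 array for each. ANO5 encodes anoctamin 5, a membrane protein of the anoctamin family, whose members include calcium-activated chloride channels and phospholipid scramblases. The series asks how ANO5 relates to the cell cycle in gastric cancer. Both arrays gave values for 17345 transcript clusters, and 14526 genes could be named. Over all clusters the arrays correlated with Pearson r = 0.969, a value across clusters, which are not independent replicates. Because each group is a single array, every difference below compares these 2 RNA samples and has no replicate check.

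ANO5 was lower in the array of cells given its siRNA. Its log2 signal was 6.83 in the control and 3.67 in the knockdown, a difference of -3.16 or 8.94-fold. None of the 500 genes nearest to it in mean level had as low a difference, the lowest of them being -1.90, while 52 of all named genes had a difference as low or lower. Genes of this low mean level (5.25) have limited room to fall, so these neighbours cannot show that the drop of ANO5 is exceptional. The knockdown value lay at or above only 4.68% of the clusters on its array, so background may set a limit to this fold, and the mean level of ANO5 lay below the measured range. Among the other anoctamins, ANO8 was 1.78-fold higher, ANO1, a calcium-activated chloride channel, 1.62-fold higher, and ANO10 1.55-fold higher. ANO6, a phospholipid scramblase, and ANO7 differed by 0.44 and 0.16 on the log2 scale. ANO3 (0.14) and ANO9 (0.24) lay below the measured range. The median of the 5 measured anoctamins was 0.63, at the 92.6th percentile of random lists, which does not stand apart.

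Differences between the arrays were broad. Of 9735 measured genes, 1086 were higher and 1104 lower by 2-fold or more in the knockdown, together 22.5%. At 3-fold or more, 343 were higher and 522 lower. For scale, the 105 olfactory receptor genes in the table, which most tissues do not express, had differences with an SD of 0.42, and 2 of them reached 2-fold. The 46 cytosolic ribosomal protein genes had a median of -0.07 and an SD of 0.29, and 2 of them reached 2-fold. These gauge the spread between genes on this pair of arrays, not between cultures. The median level was 4.14 for the olfactory receptor genes, below the measured range, and 16.1 for the ribosomal protein genes. Neither set thus gauges the spread of genes at middle levels.

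The largest negative difference of all measured genes was that of CDK2, the kinase that drives entry into S phase, at 12.01 in the control and 6.26 in the knockdown (53.8-fold lower). Next were DTL, a substrate receptor of a ubiquitin ligase that acts in S phase (27.7-fold lower), and RABL3, a small GTPase (20.1-fold). CKS1B, a subunit of CDK complexes, was 19.3-fold lower and LMNB1, a nuclear lamin, 19.2-fold lower. IFRD2 was 18.5-fold lower, PLK1, a mitotic kinase, and GINS1, part of the replicative helicase, 17.9-fold each, and CDK6 17.1-fold. XRCC2, a recombination protein, was 14.7-fold lower, POGLUT3, a glucosyltransferase, 14.5-fold and DSG2, a desmosomal cadherin, 14.4-fold. The largest positive differences were those of NDRG4 (29.9-fold higher), CYP3A5, a drug-metabolising cytochrome P450 (24.9-fold), and PLCXD1 (23.4-fold). PLCXD1 has another cluster in the table, which gave a log2 difference of 4.99 beside 4.55. By their identifiers these clusters belong to the X and the Y chromosome. They may read the same transcript and are not independent measurements. REG4, a secreted lectin of the gut, was 19.7-fold higher, and CIDEB and CIDEC, proteins of lipid droplets, 17.9-fold and 16.7-fold. DHRS9, a retinol dehydrogenase, was 17-fold higher, SPRR1A, a protein of the cornified envelope, 16.7-fold, and APOD, a lipid-binding apolipoprotein, 16.6-fold. SEMA7A was 16-fold higher, BNIPL 15.6-fold and MAPRE3, a microtubule end-binding protein, 15.0-fold. Several of these folds rest on a low value on 1 of the arrays. Examples are the control values of DHRS9 (4.35) and CIDEC (4.76) and the knockdown value of CDK6 (4.71). Background may limit such folds, so the order within each set of 12 is uncertain.

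Genes of the cell cycle were lower as groups. All 36 measured DNA replication genes were lower by at least 1.5-fold, as were all 29 measured replication-dependent histone genes, 41 of 42 genes of G2/M and mitosis and 19 of 24 G1/S regulators. The median differences were -2.37 for replication (5.17-fold), -2.50 for histones (5.66-fold), -2.02 for mitosis (4.06-fold) and -1.70 for G1/S (3.25-fold). Each of the 4 medians was lower than all 10000 random lists matched on level. The SD over members was 0.75, 0.84, 0.69 and 1.64 in the same order.

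**Figure D1:**
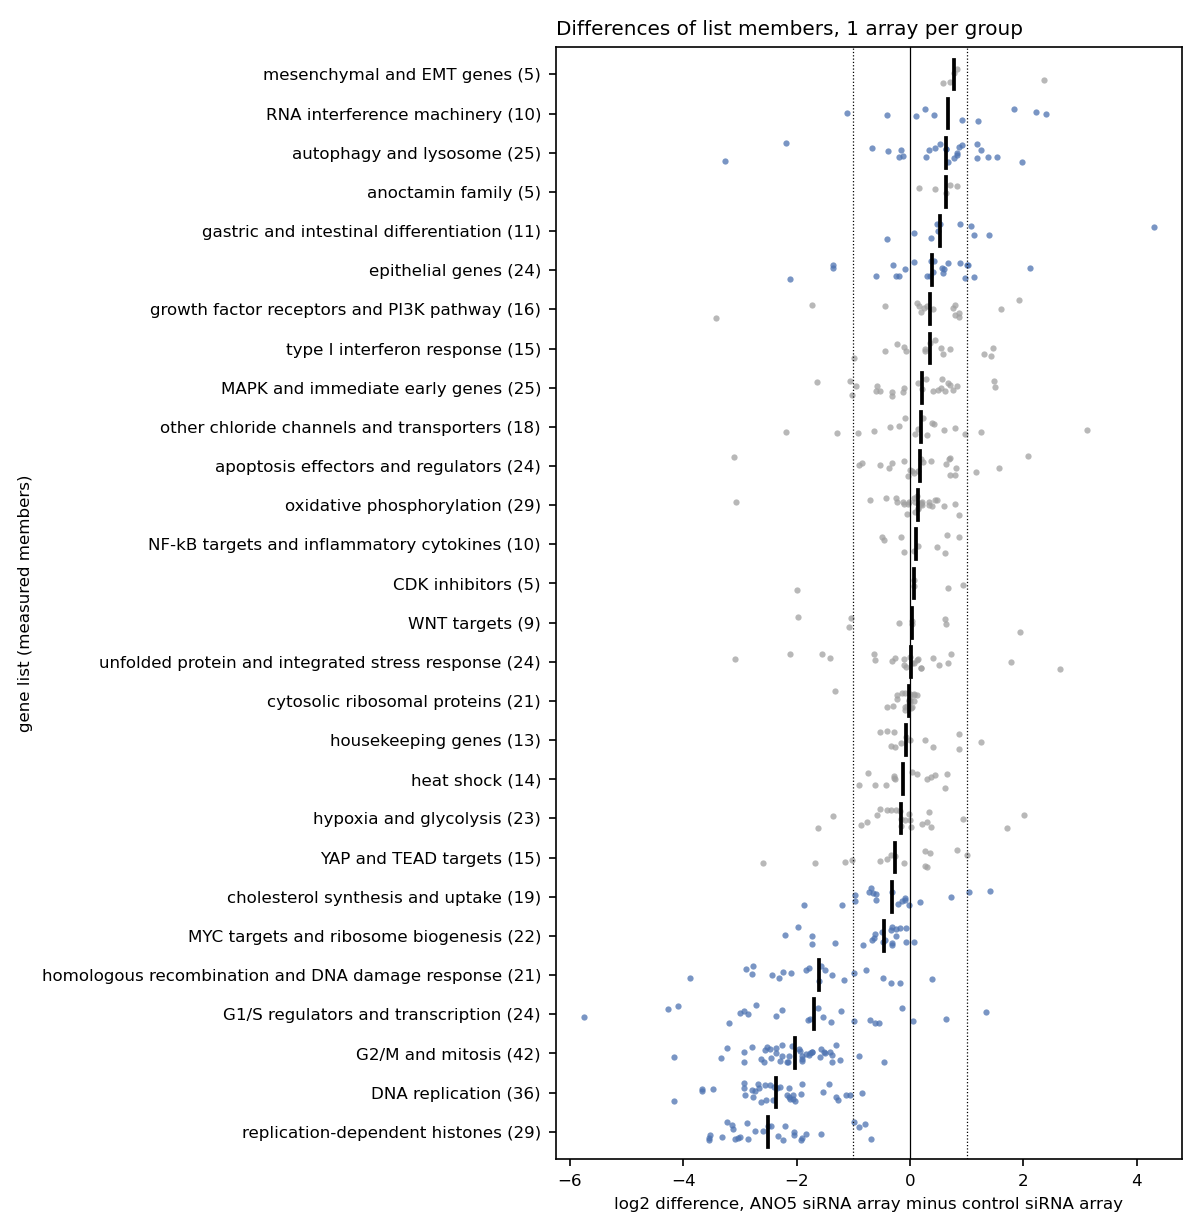
Log2 differences (horizontal axis, ANO5 siRNA array minus control siRNA array) of the measured members of the reported gene lists with at least 5 of them (vertical axis, member count in parentheses). Points are genes with random vertical jitter, black bars are list medians, dotted lines mark 2-fold, and blue lists stand apart from 10000 random lists; the 5 lowest medians run from -2.50 for histones to -1.60 for homologous recombination.

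Among G1/S regulators the cyclin-dependent kinases CDK2, CDK6 and CDK4 had log2 differences of -5.75, -4.10 and -2.71. The cyclins CCNE2 and CCNA2 were 4.76-fold and 5.17-fold lower, and CCNE1 1.62-fold lower. The transcription factors MYBL2 and E2F1 were 9.19-fold and 7.95-fold lower, and RB1, the retinoblastoma protein that restrains E2F factors, 3.41-fold lower. Against this direction, E2F3 was 2.53-fold higher and CCND1, cyclin D1, 1.56-fold higher, while CCND3 differed by 0.06. The knockdown values of CDK6 (4.71), E2F1 (5.13) and CCNE2 (5.77) were low, so background may limit the differences of these 3 genes. MDM2, a ubiquitin ligase outside this list, differed by -0.12. In replication, GINS4 and GINS2 were each 12.6-fold lower and TK1, thymidine kinase, 11.1-fold lower, whereas PCNA, the sliding clamp, was 1.8-fold lower. In mitosis, AURKB was 10.1-fold lower, UBE2C 9.38-fold, PTTG1 (securin) 7.62-fold, CDK1 6.19-fold, CCNB1 3.76-fold and the proliferation marker MKI67 2.99-fold lower. The histone genes H3C2 and H1-5 were 11.7-fold lower, H2BC8 11.6-fold and H3C8 9.92-fold. Histone genes are near-identical copies, so probes may share signal between them and single members are uncertain. The histone members need not be independent measurements, which their count and their rank among random lists do not allow for.

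**Figure D2:**
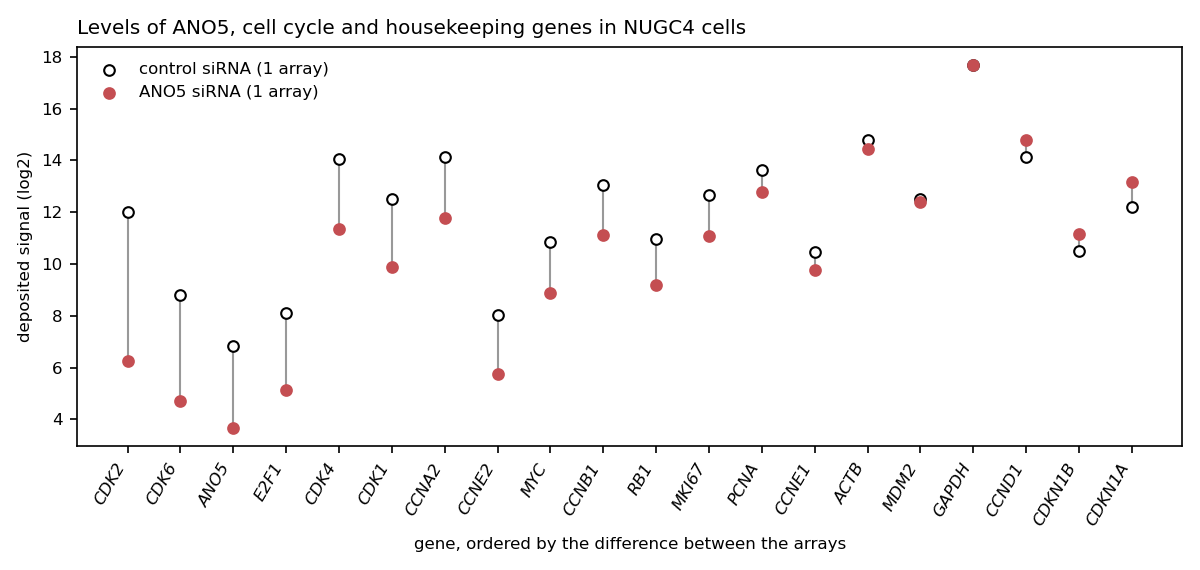
Deposited log2 signal (vertical axis) of ANO5 and the preset cell cycle and housekeeping genes (horizontal axis, ordered by difference) in the control siRNA array (open circles) and the ANO5 siRNA array (filled circles), 1 array each. CDK2 moves from 12.01 to 6.26, GAPDH stays at 17.67 and 17.68, and CDKN1A lies at 12.22 and 13.15.

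The CDK inhibitor list did not move one way. CDKN1A (p21) was 1.91-fold higher and CDKN1B (p27) 1.59-fold higher, CDKN1C and CDKN2D differed by 0.08 and 0.07 on the log2 scale, and CDKN3, a phosphatase that acts on CDKs, was 3.97-fold lower. The median of the 5 measured members was 0.08 and the mean -0.05, at the 49.1st percentile of random lists for the median.

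Genes of homologous recombination and the DNA damage response were lower: 17 of 21 by at least 1.5-fold and 0 higher, with a median of -1.60, lower than all 10000 random lists. FANCI was 7.46-fold lower, and NBN differed by 0.39. Apoptosis genes went both ways, with 9 of 24 higher and 3 lower and a median of 0.17 at the 72.8th percentile. BCL2L11 (BIM), which promotes cell death, was 4.23-fold higher, and XIAP, which restrains caspases, 2.97-fold higher. CASP2 was 8.57-fold lower and HRK 1.87-fold lower.

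Lists of growth and metabolism differed in direction. MYC targets and ribosome biogenesis genes had a median of -0.46 at the 0.34th percentile, with 9 of 22 lower and 0 higher. MYC itself was 3.92-fold lower and WDR12, a ribosome assembly factor, 4.59-fold lower, and the highest member, POLR1B, differed by 0.07. Autophagy and lysosome genes had a median of 0.64 at the 99.9th percentile, with 14 of 25 higher and 3 lower. ATG16L1 was 3.94-fold and the initiating kinase ULK1 2.89-fold higher, but LAMP1, a lysosomal membrane protein, was 9.65-fold and ATG3 4.53-fold lower. By the mean (0.37) this list lay at the 96.9th percentile and did not stand apart. Cholesterol synthesis genes had a median of -0.32 at the 1.53rd percentile, with 9 of 19 lower and 3 higher. SREBF2, the factor that induces the pathway, was 3.63-fold and HSD17B7 2.28-fold lower, while TM7SF2 was 2.68-fold and STARD4 2.06-fold higher. By its mean this list did not stand apart (4.88th percentile), nor did it against unmatched random lists (2.5th).

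Oxidative phosphorylation genes had a median of 0.14 at the 64.9th percentile, and 24 of 29 lay within 1.5-fold. ATP5MC1 was 8.34-fold lower, SDHD 1.64-fold lower, SDHA 1.83-fold higher and COX5B 1.73-fold higher. Hypoxia and glycolysis genes had a median of -0.15 (7.07th percentile), with the hexokinases HK2 and HK1 4.06-fold and 3.29-fold higher, ADM 3.09-fold lower and EGLN3 2.57-fold lower. Of 21 cytosolic ribosomal protein genes, 20 lay within 1.5-fold. RPL19 was 2.5-fold lower, RPL10A, RPL38 and RPS6 differed by -0.40, 0.13 and 0.08, and the median was -0.02 (29.6th percentile).

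Of the lists of cell identity, the gastric and the epithelial one stood apart by their medians. Gastric and intestinal differentiation genes had a median of 0.54 at the 97.9th percentile, and did not stand apart with the filter at the 50th percentile of mean level (96.4th percentile) or against unmatched random lists (96.6th). Of 11 measured members, 5 were higher and 0 lower by 1.5-fold, led by REG4 and by CEACAM5, an adhesion protein (2.62-fold). CDX2, an intestinal transcription factor, differed by -0.40. Epithelial genes had a median of 0.39 at the 98.4th percentile, with 9 of 24 higher and 4 lower. KRT7 was 4.35-fold and DSP, desmoplakin, 2.19-fold higher, and MAL2 4.35-fold and CLDN3 2.55-fold lower. By its mean (0.22) the epithelial list lay at the 89.6th percentile and did not stand apart, nor did it against unmatched random lists (96.8th). Only 5 of 25 mesenchymal genes were in the measured range. All 5 were at least 1.5-fold higher, among them the fibronectin receptor subunit ITGA5 (5.17-fold) and TGFB1 (1.78-fold), and the median of 0.78 lay at the 96.8th percentile, which does not stand apart. Without the filter on low values the 14 members in the table had a median of 0.16 (84.9th percentile). Of the markers of other cell types, 1 of 10 for fibroblasts, 4 of 12 for blood and 3 of 14 for endothelium, muscle and nerve were in the measured range. Their medians were -0.11, -0.27 and 0.51, at the 43.6th, 20.2nd and 86.5th percentiles. LYZ was 2.11-fold lower, COL1A2, CD68, HBA1 and ACTN2 differed by -0.11, -0.32, 0.16 and -0.14, and VWF and SYP by 0.52 and 0.51.

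Components of the RNA interference machinery had a median of 0.68 at the 98.3rd percentile. The list did not stand apart without the filter on low values (median 0.43, 91.7th percentile) or with the filter at the 50th percentile (96.5th). Of 10 measured members, 5 were higher and 1 lower. AGO2, the argonaute that cleaves target RNA, was 5.32-fold and TNRC6B 4.66-fold higher, while XPO5 was 2.16-fold lower and AGO1 differed by -0.41. Both cultures had received siRNA.

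The lists that follow did not stand apart. Type I interferon genes had a median of 0.35 (93.7th percentile). OASL and OAS1 were 2.75-fold and 2.69-fold higher, IFIH1 was 1.97-fold lower and DDX60 differed by -0.44. NF-kB targets had a median of 0.10 (59.3rd percentile), with TNFSF10 1.81-fold and NFKB1 1.57-fold higher, and TNFAIP3 and LIF at -0.50 and -0.46. The unfolded protein and integrated stress response list had a median of 0.03 and a mean of -0.11 (33.8th percentile for the median). In it SLC7A11, a cystine transporter, was 6.28-fold and EDEM1 3.46-fold higher, and MANF was 8.52-fold and PHGDH 4.32-fold lower. Heat shock genes had a median of -0.12 (14.9th percentile), with HSPD1 1.87-fold and HSPA4L 1.67-fold lower, and DNAJA1 1.58-fold and HSPB1 1.54-fold higher.

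Among signalling lists, growth factor receptor and PI3K genes had a median of 0.35 (91.1st percentile). AKT2 was 10.7-fold and IGF1R 3.29-fold lower, and FGFR3 3.81-fold and GSK3B 3.05-fold higher. YAP and TEAD targets had a median of -0.26 (7.12th percentile), with the factors TEAD1 and TEAD4 themselves 6.06-fold and 3.20-fold lower, AAK1 2-fold higher and MYOF 1.79-fold higher. Immediate early and MAPK genes had a median of 0.21 (79.6th percentile), with EGR1 2.83-fold and DUSP5 2.79-fold higher, SPRY1 3.12-fold lower and SPRY2 2.07-fold lower. WNT targets had a median of 0.03 and a mean of -0.11 (41.5th percentile for the median), with DKK1 3.84-fold higher and SOX9 2.11-fold lower. Other chloride channels and transporters had a median of 0.19 (73.5th percentile), among them CLIC3 at 8.75-fold and SLC12A7 at 2.38-fold higher, and LRRC8B at 4.53-fold and CLCN5 at 2.43-fold lower.

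Of 13 housekeeping genes, 10 lay within 1.5-fold. GAPDH, ACTB, HPRT1 and PGK1 differed by 0.01, -0.34, -0.52 and -0.41, while POLR2A was 2.40-fold higher. The housekeeping median was -0.06 and the mean 0.13, at the 26.6th percentile for the median. Of the 31 lists reported, 11 stood apart by their medians, 7 lower and 4 higher, where chance gives 1.55 for lists of unrelated genes. Members of a list are co-regulated, and lists such as those of replication, mitosis and histones can move together. The 11 are thus not a count of separate findings.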

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

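Of the 2801 clusters with no gene name here, which none of the comparisons above uses, 1440 were in the measured range, and 143 of these were higher and 139 lower by 2-fold or more in the knockdown array. Together this is 19.6% of them, beside 22.5% of the named genes.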

How the results depend on the processing

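ANO5 differed by -3.17 after loess and -3.14 after quantile normalization. Centring on the median moved no gene, the 75th percentile scaling moved all by 0.02, and ANO5 has 1 cluster, so the other alternatives could not test it. Between 9 and 12 of the 32 lists stood apart under the alternatives run on them. Loess on the mean level gave 897 higher and 1237 lower genes, beside 1086 and 1104, and no scaling moved the median of the measured genes by over 0.085. The count of higher genes moved to 2257 at 1.5-fold and 343 at 3-fold, and that of lower genes to 1961 and 522, because the threshold itself changed. Counting the unnamed clusters too, chosen after seeing the data, gave 1231 and 1243. The CDK inhibitor median moved to 0.67 with the filter at the 50th percentile, which keeps fewer members. With that filter the NF-kB median moved from 0.10 to 0.36, that of WNT targets from 0.03 to 0.33 and that of blood markers from -0.27 to -1.08, and loess moved that of oxidative phosphorylation from 0.14 to 0.0025. None of these 4 stood apart at either value. Without a filter the NF-kB median was -0.10 and that of WNT targets -0.20. The medians of the G1/S, replication, mitosis and histone lists, and their means, kept their direction and stood apart under all alternatives run on them, at -1.82 to -1.52, -2.43 to -2.34, -2.14 to -2.02 and -2.57 to -2.41. The calls of the cholesterol, epithelial, gastric, autophagy and RNA interference lists were each lost under 1 or 2 alternatives. Type I interferon genes stood apart only without a filter (98.3rd percentile) and mesenchymal genes only by their mean (99.1st percentile). Of 760 values of single named genes under alternatives, 753 stayed on their side of 2-fold, and the others were those of AAK1, STARD4 and IFIH1, which lie next to it. This count is a weak check. Centring and the 75th percentile scaling could hardly move a value, and the median over clusters bears only on genes with more than 1 cluster. No paired analysis was possible because each group has 1 array, and for the same reason no replicate could be left out. Genes near background limit what can be seen: a fold against a low value, such as that of ANO5, may be understated, and the pseudocount, which shrinks such genes, left 875 higher and 934 lower.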

Other observations

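Every test in this part was chosen after the differences had been seen. Measured genes were grouped by the letters before the first digit of their symbol, and the 162 such families with at least 8 members were set against random lists in the same way as the gene lists. In all, 21 families stood apart, where chance gives 8.1 for families of unrelated genes. Those named here as standing apart were picked from these 21 after their values were seen. The VPS genes, which sort proteins to endosomes and lysosomes, had a median of 0.72 with 17 of 33 higher and 0 lower by 1.5-fold, reached by 1 of 10000 random lists. SNX genes (sorting nexins) had a median of 0.51 (99.1st percentile) with 8 of 22 higher and 2 lower, CHMP genes of the ESCRT machinery 0.76 (99.2nd percentile) with 5 of 10 higher and 2 lower, SEC genes 0.53 with 8 of 20 higher and 0 lower, and ATG genes 0.84 with 10 of 16 higher and 2 lower, of which 8 are also in a preset list. TSPAN genes (tetraspanins) had a median of 0.95 with 7 of 12 higher and 2 lower, among them TSPAN14 at -2.05. Cytochrome P450 genes (CYP) had a median of 0.84 with 9 of 16 higher and 2 lower, above all random lists, and 0.67 without the member already named for its large difference. CYP1A1 differed by 3.87, and CYP1B1 by -2.61. AP genes, largely of the adaptor complexes of vesicle coats, had a median of 0.53 (99.6th percentile) with 11 of 26 higher and 3 lower, and DENND genes 0.62 (97.53rd percentile) with 6 of 11 higher and 1 lower. RAB, EXOC, TRAPPC, STX and TMED genes, which also act in membrane traffic, did not stand apart: RAB had a median of 0.19 (84.8th percentile), EXOC 0.25 (77.0th), TRAPPC 0.35 (89.1st), STX 0.40 (93.8th) and TMED -0.05 (28.4th).

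Among the lower families, NUP genes of the nuclear pore had a median of -0.81, with 13 of 20 lower and 0 higher. NUP210 and NUP155 differed by -2.67 and -1.98. EXOSC genes of the RNA exosome had a median of -0.73 (1.31st percentile) with 5 of 9 lower and 1 higher. UTP genes of ribosome assembly had a median of -0.49 (2.18th percentile) with 2 of 10 lower and 0 higher, and CEP genes of the centrosome -0.36 (0.49th percentile) with 11 of 32 lower and 3 higher. GALNT genes, which start mucin-type glycosylation, had a median of -0.63 (1.09th percentile), with 6 of 11 lower and 2 higher, from GALNT3 at -2.38 to GALNT11 at 1.49.

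The decrease of cell cycle genes is a pattern that could have a technical source. A level-dependent difference between the arrays was small, as loess on the mean level moved no measured gene by over 0.17. The median of the 131 members of the 4 lists was thus bound to change little, at -2.30 after loess and -2.21 before. A level-dependent difference of that size does not account for the decrease. Values near background would spare bright members, but the 108 members above the 50th percentile of mean level had a median of -2.17. A difference between the cultures or arrays other than the siRNA cannot be told apart from the effect of ANO5 siRNA, since there is 1 array per group. Fewer dividing cells after loss of ANO5 remains a hypothesis, and so does an action of the siRNA on other transcripts, which would need another siRNA against ANO5 to separate.

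Zinc finger genes with the symbol ZNF, largely transcription factors, had a median of -0.25, lower than all random lists, with 95 of 294 lower and 23 higher by 1.5-fold. Values near background are not a likely source, as the 148 brighter members, above the 50th percentile of mean level, had a median of -0.29. Loess on the mean level, which moved no measured gene by over 0.17, left -0.33. A shift of chromosome 19 as a whole, where 146 of them lie, is argued against by its 529 measured genes that are not ZNF genes, with a median of 0.07. ZNF genes on chromosome 19 had a median of -0.35 and those elsewhere -0.12. Of random splits of the ZNF genes, 0.35% gave as large a gap, so the decrease was larger for those on chromosome 19. The splits treat ZNF genes as independent, and the genes elsewhere were not set against random lists on their own. Signal shared between similar ZNF genes was not tested, and a difference between the 2 cultures stays open, as does an effect of ANO5 loss.

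CDK2 had the largest negative difference of the measured genes, at -5.75 beside -4.27 for CKS1B, the next G1/S regulator. ANO5, the target of the siRNA, differed by -3.16, a value that background may limit. Whether the siRNA acts on CDK2 itself was not tested. Without 182 measured genes of the cell cycle, recombination and histone families, the counts of lower against higher genes went from 1104 against 1086 to 957 against 1085 at 2-fold, from 522 against 343 to 401 against 343 at 3-fold, and from 319 against 157 to 222 against 157 at 4-fold. At 8-fold they went from 69 against 35 to 44 against 35. The genes left out were largely lower ones, so the lower counts were bound to fall. Genes outside the lists that act in S phase, such as DTL, were not left out. The excess of lower genes that remained from 3-fold on is thus not shown to lie outside the cell cycle.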
